A study of Mus musculus with 9 samples.

How the data were processed

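ATAC-seq, which reads open chromatin through transposase insertion, was done on murine alphaTC1 cells, a pancreatic alpha cell line, 5 days after transduction. The 9 libraries form 3 groups of 3: empty vector, Smndc1 shRNA and Atrx shRNA, and the labels call them individual biological replicates. The deposited table holds raw counts for 80827 consensus regions in the 9 libraries, whole numbers with no scaling, and a second deposited file gives the start and end of each region on mm10 (GRCm38). The reads were 75 bp paired-end. Per the submitters' processing notes, Bowtie2 2.4.4, SAMtools 2.8.0, deepTools 3.5.1, MACS2 2.2.7.1 and bedtools 2.27.1 were used. The role of each tool, how the consensus regions were merged and whether reads, fragments or insertion sites were counted are not given in the sources used here. All columns of the table were matched to a labelled sample (0 left unmatched).

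Library totals over the regions ran from 5.29 to 8.15 M, with a median of 28.0 to 39.0 counts per region. The regions lie on chromosomes 1 to 19 and X (1284 on X and 0 on Y), with a median width of 501 bp and a maximum of 3253 bp. Regions were placed with a table of gene bounds that gives no strand, exon or transcription start. A gene-end region is therefore 1 that overlaps a window from 1000 bp outside to 500 bp inside either end of a protein-coding gene: 12717 regions, with 33744 others in gene bodies and 34366 between genes. Of the 11717 coding genes with an end region, 86.37% have it at 1 end only, and this window stands in for the promoter window that was planned. An assigned region lies in a gene's body or has that gene's end as the nearest within 50 kb. Analyses that need a genome sequence (motifs, base composition, G-quadruplex patterns, repeats) or exons were not run.

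The test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr (minimum count 10), robust dispersion, all 9 libraries in 1 fit and 1 coefficient per group. It covered 80345 regions (482 fell below the filter), and a region was called when its Benjamini-Hochberg adjusted p was under 0.05. Fold changes are log2 with their standard error (SE); levels are TMM-normalised CPM (counts over library size in M), mean and SD of 3 libraries. All adjusted p values for regions come from this edgeR model unless another tool is named. An alternative fixed in advance, called trended offsets here, uses a loess curve of each library against mean log2 count as edgeR offsets. This makes libraries that differ in the contrast between strong and weak regions alike. The text says which of the 2 fits a count or value comes from. On simulated data made from these counts, the TMM fit was tested and called 25 of 100 regions changed 2-fold and 73 of 100 changed 4-fold, with 4 unchanged regions among 102 calls. With trended offsets it called 33 and 84, with 3 among 120. The simulated libraries were drawn independently and, for the TMM fit, without differences in contrast, so these error counts need not hold for the real libraries.

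Named regions follow a rule: adjusted p under 0.05, mean log2 CPM of at least 1, and all 3 libraries of the shRNA on the same side of all 3 libraries compared with. Of those, the 6 gene-end and 5 other regions with the highest and the lowest fold change are named for each comparison with empty vector, and 4 and 3 for Smndc1 shRNA against Atrx shRNA. Also named are up to 4 called members of each gene list and 24 key genes (hormones, islet regulators and the targeted genes, each with 10 kb on both sides). The rule was also applied to the fit with trended offsets, on levels corrected by those offsets, a choice made after the data were seen. The tests, gene lists, key genes, named-region rule and most alternatives were fixed before the data were examined. Of 31 gene lists (24 by symbol and 7 by name pattern), a histone list matched 0 genes; 28 could be tested at gene ends and 30 over assigned regions, beside 9 classes of region. Lists and classes were tested with camera of limma 3.58.1 (log2 CPM with a prior count of 2, preset correlation 0.01, two-sided, adjusted over the lists of a comparison), and again with an estimated correlation. Tested on simulated data, camera gave a raised list p = 5.43e-16 with the preset and 9.28e-05 with an estimated correlation. Regions were drawn independently of each other there, so lists whose members vary together were not tested.

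Alternatives were DESeq2 1.42.0, limma voom, other size factors, no filter or a mean count of at least 50, 6 libraries, stricter thresholds, each library left out in turn, and replicate 3 of every group left out. The replicate numbers were not treated as pairs. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Accessibility at Smndc1 and Atrx is no check of the knockdowns, since an shRNA acts on the RNA.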

Results

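Open chromatin was compared in alphaTC1 cells carrying an shRNA against Smndc1, a splicing factor with a Tudor domain, an shRNA against Atrx, a chromatin remodeler, or an empty vector. Group totals were alike within their spread: 6.15 ± 0.656 M counts with Smndc1 shRNA, 5.92 ± 0.815 with Atrx shRNA and 7.05 ± 1.16 with empty vector (mean ± SD, n = 3 each). The libraries differ in contrast, and that split does not follow the groups. The strongest 10% of regions hold 38.6% of counts in replicate 3 of Atrx shRNA, 38.8% in replicate 3 of empty vector and 38.5% in replicate 3 of Smndc1 shRNA. In the other 6 they hold 43.3% to 48.8%. Group means of this share are 43.9 ± 5.13%, 43.6 ± 4.14% and 43.1 ± 4.53%. At the targeted genes themselves, the end region of Smndc1 stood at 44.5 ± 9.58 CPM with its shRNA and 49.3 ± 9.10 with empty vector (adjusted p = 0.939). That of Atrx stood at 20.2 ± 6.51 and 22.1 ± 6.25 (adjusted p = 0.987).

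With Smndc1 shRNA, accessibility fell at 109 regions and rose at 16. A region inside Dbnl, which encodes a drebrin-like actin-binding adaptor, rose from 7.35 ± 1.05 to 25.0 ± 3.30 CPM (log2 fold change 1.77 ± 0.24 SE, adjusted p = 8.87e-06, n = 3 per group). A region at an end of Zc3h10, a zinc finger gene, fell from 24.2 ± 1.68 to 9.50 ± 0.912 CPM (-1.35 ± 0.23, adjusted p = 0.00223). At Ccn3, which encodes a secreted matricellular protein, the end region fell from 14.3 ± 1.66 to 5.62 ± 0.768 (-1.34 ± 0.25, adjusted p = 0.00657). At the end of Itih3, an inter-alpha-trypsin inhibitor heavy chain gene, the level fell from 6.85 ± 1.33 to 1.65 ± 0.746 (-2.06 ± 0.47, adjusted p = 0.0335). The gene-end region that rose lies at Elob, the elongin B gene, and is also assigned to Srrm2, a splicing coactivator (1.09 ± 0.23, adjusted p = 0.022). In each of these, all 3 Smndc1 shRNA libraries lie beyond all 3 empty vector libraries, which the naming rule requires.

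The other gene-end regions named by the rule, both lower, are at Akap3 (-1.28 ± 0.26) and Gm52363 (-1.09 ± 0.24). Away from gene ends, regions 264.53 kb from Grin2a (2.08 ± 0.50, adjusted p = 0.0499) and 950.34 kb from Mat2b (1.89 ± 0.32, adjusted p = 0.00195) rose. So did regions inside Snap47 (1.63 ± 0.38) and Rnf32 (1.38 ± 0.31). Regions inside Unc80 (-1.84 ± 0.35), a subunit gene of a sodium leak channel, and Bcl2 (-1.80 ± 0.40), the apoptosis inhibitor, fell. Regions 559.52 kb from D3Ertd751e (-1.80 ± 0.39), 75.25 kb from Bcor (-1.78 ± 0.36, on X) and 48.73 kb from Nrxn3 (-1.61 ± 0.38) fell too. By place, 1 gene-end region was higher and 5 lower, against 10 and 54 in gene bodies and 5 and 50 between genes. With trended offsets gene ends are not spared: 75 were higher and 82 lower there, against 154 and 267 in gene bodies and 104 and 225 between genes. With trended offsets 333 regions were higher and 574 lower, and all 125 calls above are among them. The lower share is 63.3%, against 87.2% with TMM factors. Its named gene-end regions add Hmox1 (heme oxygenase; 1.53 ± 0.39, adjusted p = 0.0159), Zfp239 (1.60), Zfp692 (1.31), Rnpepl1 (1.23) and Cbln4 (1.23), higher, and Smc4/Trim59 (-2.26) and Olfr1347 (-1.63), lower. Elsewhere it adds, higher, regions near Lmnb1 (2.50), inside Tmem131 (2.05), 90.18 kb from Zfp637 (2.37) and 287.37 kb from Prmt6 (2.05). Lower are regions inside Dync1i1 (-2.21) and Amph (-2.21), near Rnf138rt1 (-2.13) and Zfhx4 (-2.08), and 385.21 kb from Sqor (-2.04).

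The number of these calls depends on which library is left out, controls included. Leaving out 1 of 3 libraries also lowers power, so a lost call by itself does not show a smaller fold change. The count of 125 became 1 without empty vector replicate 1 (Dbnl, 1.66, adjusted p = 0.00633), 13 without empty vector replicate 2, 16 without Smndc1 shRNA replicate 1 and 77 without its replicate 2. By contrast, 609 were called without empty vector replicate 3 and 254 without Atrx shRNA replicate 3. With the replicate number as a block the count was 1268, and without replicate 3 of every group 614. Of the 16 named regions above, 1, 4, 4 and 10 were still called without the first 4 of these, and 12 without Smndc1 shRNA replicate 3. With trended offsets the count of 907 became 251, 227, 448 and 581 without empty vector replicates 1 and 2 and Smndc1 shRNA replicates 1 and 2. Of 32 named regions that pass with trended offsets, 9 were called whichever library was left out, among them Dbnl (highest adjusted p = 3.68e-05), Zc3h10 (0.00208), Mat2b (0.00382), Ccn3 (0.0349), Elob (0.0452) and Itih3 (0.0494).

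**Figure D1:**
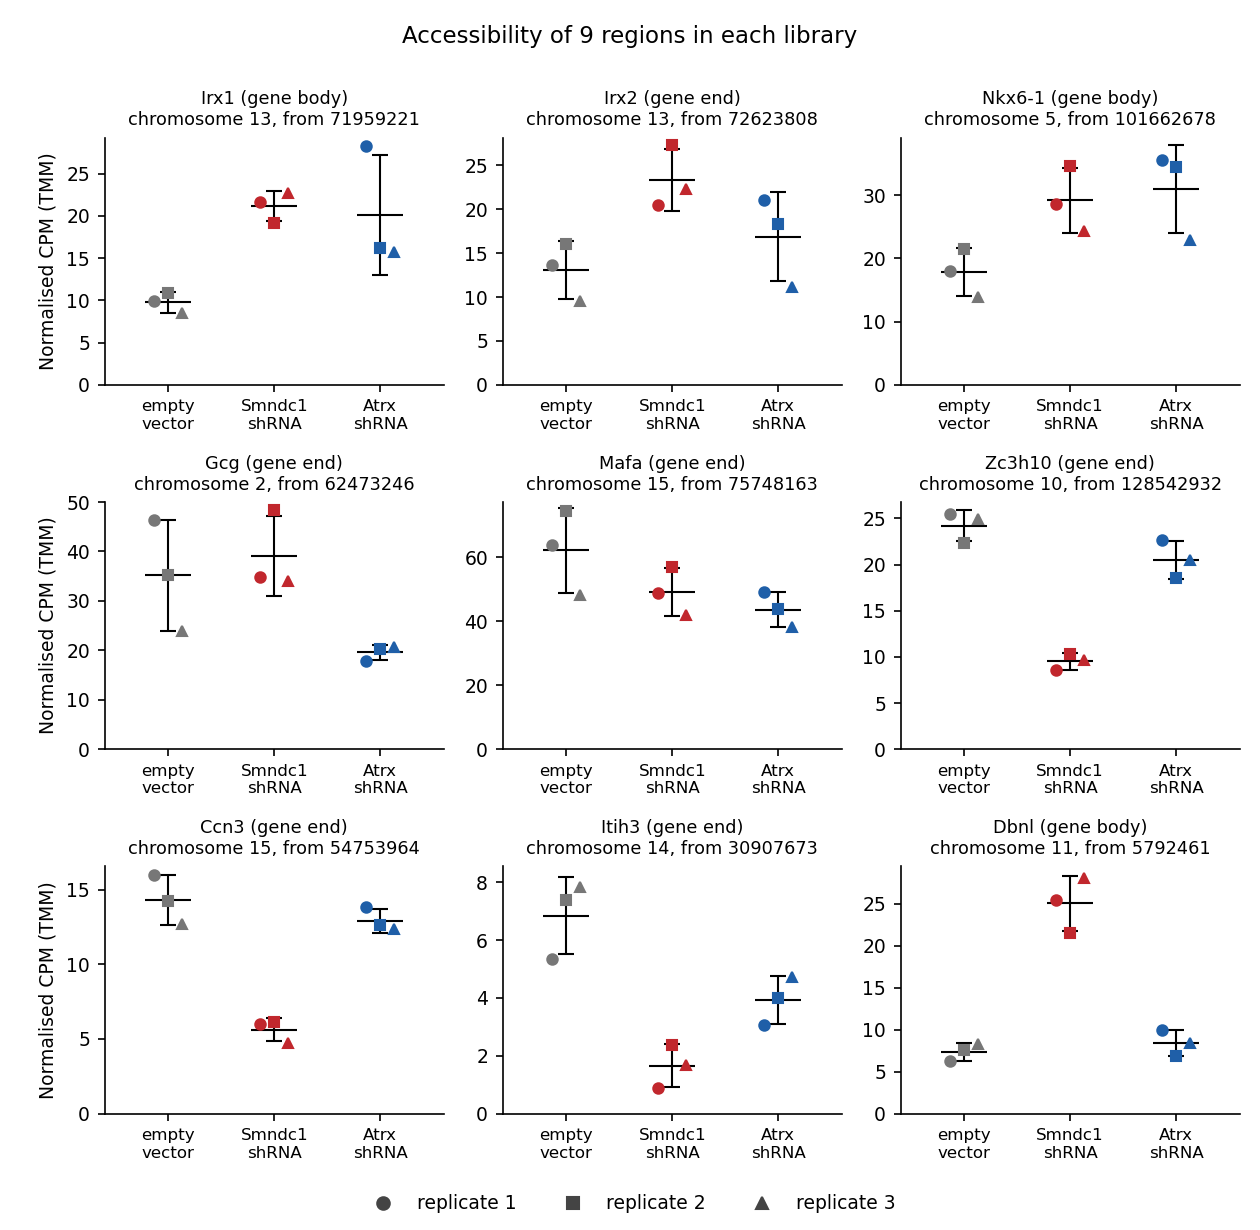
Accessibility at 9 regions in each library, in TMM-normalised CPM; points are libraries, bars mean ± SD of 3. Dbnl stands at 25.0 ± 3.30 with Smndc1 shRNA and 7.35 ± 1.05 with empty vector, and Gcg at 19.6 ± 1.51 with Atrx shRNA and 35.2 ± 11.2 with empty vector.

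Among regulators of islet identity, accessibility rose at Irx1 and Irx2, Iroquois homeobox genes active in alpha cells. A region inside Irx1 went from 9.76 ± 1.23 to 21.1 ± 1.81 CPM with Smndc1 shRNA (1.11 ± 0.24, adjusted p = 0.022; trended 1.20 ± 0.21, adjusted p = 0.000111), in 3 of 3 libraries. With trended offsets the end regions of Irx1 (0.77 ± 0.17, adjusted p = 0.00284) and Irx2 (0.91 ± 0.20, adjusted p = 0.00389; 23.4 ± 3.54 against 13.1 ± 3.30 CPM) rose too. So did regions at Nkx6-1, a beta cell homeobox gene (0.78 ± 0.17, adjusted p = 0.00282), Neurod1 (0.54 ± 0.15) and Pcsk2, whose product cleaves proglucagon (0.64 ± 0.17). Of 121 regions at 22 of the key genes, 1 rose and 0 fell with TMM factors in edgeR (3 and 0 adjusted over the list alone). With trended offsets 8 rose and 1 fell (18 and 1 adjusted over the list alone). The Irx1 body call with TMM factors ended without empty vector replicate 1 (1.12, adjusted p = 0.253), empty vector replicate 2 (1.20, adjusted p = 0.114) and Smndc1 shRNA replicate 1 (1.10, adjusted p = 0.148). With trended offsets it held in 9 of 9 fits. The Irx1 end lost its call without empty vector replicate 2 (0.68, adjusted p = 0.103). Irx2 and Nkx6-1 lost theirs without empty vector replicate 1 (0.89, adjusted p = 0.0591, and 0.72, adjusted p = 0.063). Neurod1 and Pcsk2 each lost theirs without any 1 of several libraries, empty vector replicate 1 among them (adjusted p = 0.137 and 0.306).

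Across the list of endocrine transcription factors, 6 of 252 assigned regions rose and 0 fell with Smndc1 shRNA and trended offsets in edgeR (7 and 0 adjusted over the list alone; 0 called with TMM factors). They include 3 regions at Prox1, a homeobox gene of islet development (0.83 ± 0.15, adjusted p = 0.000217 for the strongest, called in 9 of 9 fits without 1 library). The others are at Insm1 (0.56 ± 0.14), Foxa2 (0.54 ± 0.14) and Neurod1, given above. Alpha cell markers had 5 regions higher and 1 lower of 166 (5 and 1 adjusted over the list alone; 1 and 0 with TMM factors), Irx1, Irx2 and Pcsk2 against Nxph1 (-1.30 ± 0.35). Of 104 regions of p53 targets, 4 rose and 2 fell (5 and 5 adjusted over the list alone; 0 and 0 with TMM factors). Regions at Cdkn1a, the p21 gene (0.55 ± 0.13), Bbc3, which encodes Puma (0.44 ± 0.11), and Gadd45a (0.51 ± 0.14) rose. Xpc (-0.83 ± 0.19) and another region of Gadd45a (-0.48 ± 0.12) fell. Of the 289 regions of splicing factors 3 rose and 0 fell (3 and 0 adjusted over the list alone; 1 and 0 with TMM factors): Srrm2, Ddx39b (0.86 ± 0.21) and Srsf1 (0.53 ± 0.14). Without empty vector replicate 1 the calls at Insm1 (adjusted p = 0.304), Foxa2 (0.247), Nxph1 (0.0935), Cdkn1a (0.124), Bbc3 (0.0887), Ddx39b (0.0872) and Srsf1 (0.264) ended, as did those of both Gadd45a regions (0.209 and 0.191). Xpc lost its call without empty vector replicate 2 (0.199). Other libraries ended some of them as well.

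As sets, the 8 keratin genes with an end region were higher with Smndc1 shRNA (median 0.49, 7 of 8 positive, camera adjusted p = 0.00874). With trended offsets the median is 0.58 and does not pass (adjusted p = 0.0577), so the call ended without a smaller shift, and adjusted p = 0.954 with an estimated correlation. It also ended without empty vector replicate 1 (0.30, adjusted p = 0.173) and without Smndc1 shRNA replicate 3 (0.41, adjusted p = 0.284). Genes of cholesterol synthesis were lower with trended offsets (median -0.12, 17 of 19 negative, adjusted p = 0.0068; 0.0929 with TMM factors), and adjusted p = 0.491 with an estimated correlation. Over assigned regions the endothelial list (0.28, adjusted p = 0.0175; trended 0.31, adjusted p = 0.0604) and the endocrine transcription factors (0.21, adjusted p = 0.0482; trended 0.20, adjusted p = 0.0554) were higher with TMM factors. Adjusted p = 0.949 and 0.372 for them with an estimated correlation. The endothelial call ended without empty vector replicates 1 and 2 (adjusted p = 0.334 and 0.0852) and Smndc1 shRNA replicates 1 and 3 (0.0954 and 0.226). Its medians there were 0.13, 0.22, 0.37 and 0.06 in that order. The endocrine call ended without any 1 library other than Atrx shRNA replicate 1 (0.0555 to 0.283), with medians of 0.17 to 0.22, near that of the full fit.

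With Atrx shRNA, Gcg, the glucagon gene, had lower accessibility at its end region once the contrast of the libraries was made alike. It stood at 19.6 ± 1.51 CPM against 35.2 ± 11.2 with empty vector (trended -0.78 ± 0.16, adjusted p = 0.00373), below all controls in 3 of 3 libraries. The region lies just outside the lower-coordinate bound of Gcg, and with no strand given it cannot be read as the promoter. Of 7 regions within 10 kb of Gcg it is the only called region. Regions at ends of Rubcn, an autophagy regulator (-0.62 ± 0.12, adjusted p = 0.00274), and Gng7, a G protein subunit gene (-0.73 ± 0.16, adjusted p = 0.00917), fell too. The end region of Wdr88 rose from 9.32 ± 3.88 to 21.6 ± 4.12 CPM (1.29 ± 0.23, adjusted p = 0.000851). In all, 158 regions were higher and 58 lower with trended offsets. With TMM factors, all 9 libraries and no block, edgeR called 0 regions (4618 at an unadjusted p under 0.05), DESeq2 called 0 (3835) and limma voom 0 (4394). In that edgeR fit Gcg has -0.85 ± 0.25 with adjusted p = 0.47, and the smallest adjusted p of any region is 0.202. The regions named for Atrx shRNA in this part were picked from the fit with trended offsets and do not pass in that one. Other fits with TMM factors do make calls. With the replicate number as a block edgeR called 231 regions, 148 of them among the 216 above, and without replicate 3 of every group 91, 53 of them among the 216. It called 22 without Smndc1 shRNA replicate 3, 10 without Atrx shRNA replicate 3, 3 without empty vector replicate 3, Snap47 among them (2.24, adjusted p = 0.00689), and 18 with 6 libraries. Replicate 3 of every group has low contrast, and the deviations of these 3 libraries from their group means correlate at 0.313 to 0.419 across regions, which are not independent replicates.

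By place, the trended calls are 40 higher and 21 lower at gene ends, 72 and 16 in gene bodies and 46 and 21 between genes. Higher gene-end regions named by the rule are at Zfp239 (1.76), Gm39270 (1.53), Zfp692 (1.38), Dcaf7 (1.32) and H2ac15, a histone gene (1.28), beside Wdr88. Lower ones are at Fhdc1 (-0.83) and Tmem241 (-0.75), beside Gcg, Gng7 and Rubcn. Regions near Olfr1329, Gm20939 (2.07) and Rfxap (1.60) and inside Snap47 (1.92 ± 0.37, adjusted p = 0.0023) and Arid5b (1.81) were higher. Regions near Ptpdc1 (-1.75) and Gm5148 (-1.54), inside Cdh9 (-1.59), 155.62 kb from Flrt2 (-2.05) and 98.46 kb from Ptger3 (-1.52) were lower. The count of 216 became 23 and 34 without empty vector replicates 1 and 2, 19 and 27 without Atrx shRNA replicates 1 and 2, 140 without Smndc1 shRNA replicate 1 and 451 without its replicate 3. Of the 22 named regions 0 were called whichever library was left out. Gcg lost its call without empty vector replicate 1 (-0.60, adjusted p = 0.261) and Atrx shRNA replicates 1 (-0.62, adjusted p = 0.195) and 2 (-0.79, adjusted p = 0.0717). Rubcn lost it without Atrx shRNA replicates 1 and 2 (0.0802 and 0.0583), and Wdr88 without empty vector replicate 2 (0.0603) and Atrx shRNA replicate 2 (0.0522).

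Islet regulators moved with Atrx shRNA in both directions, all with trended offsets. The region inside Irx1 stood at 20.1 ± 7.09 CPM (1.10 ± 0.22, adjusted p = 0.00253). That at Nkx6-1 rose from 17.8 ± 3.80 to 30.9 ± 6.98 (0.83 ± 0.17, adjusted p = 0.0043). There were gains at the Irx1 end (0.72 ± 0.17), Pax6 (0.79 ± 0.20, adjusted p = 0.0423) and Nkx2-2 (0.63 ± 0.16, adjusted p = 0.0423). The end region of Mafa, an activator of the insulin gene, fell from 62.2 ± 13.2 to 43.6 ± 5.42 (-0.50 ± 0.13, adjusted p = 0.0448). Of the 121 key regions 5 rose and 2 fell (10 and 2 adjusted over the list alone); edgeR with TMM factors called 0 (1 adjusted over the list alone). Of the p53 targets, 3 regions rose and 0 fell (6 and 1 adjusted over the list alone; 0 and 0 with TMM factors). They lie at Bbc3 (0.55 ± 0.11, adjusted p = 0.00405), Cdkn1a (0.58 ± 0.13, adjusted p = 0.0153) and Bax (0.64 ± 0.15, adjusted p = 0.0207). Srsf1 (0.66 ± 0.14, adjusted p = 0.00562) is the splicing factor region that rose (3 and 0 adjusted over the list alone), and Krt8 the keratin gene (0.87 ± 0.21, adjusted p = 0.0266). Without empty vector replicate 1 each of these calls ended (adjusted p = 0.0816 for Irx1, 0.133 for Nkx6-1, 0.0927 for the Irx1 end, 0.248 for Pax6, 0.313 for Nkx2-2, 0.159 for Mafa, 0.0618 for Bbc3, 0.201 for Cdkn1a, 0.279 for Bax, 0.189 for Srsf1 and 0.388 for Krt8). All but Nkx2-2 and Bbc3 also ended without Atrx shRNA replicate 1 (Irx1 0.233, Nkx6-1 0.0802, the Irx1 end 0.188, Pax6 0.335, Mafa 0.328, Cdkn1a 0.191, Bax 0.125, Srsf1 0.318 and Krt8 0.14).

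As sets at gene ends, olfactory receptors (0.30, adjusted p = 0.00121), keratins (0.25, adjusted p = 0.0476) and splicing factors (0.07, adjusted p = 0.0476) were higher with Atrx shRNA by camera with TMM factors. The protocadherin clusters (-0.24, adjusted p = 0.0476) and the interferon response (-0.13, adjusted p = 0.0476) were lower. Adjusted p = 0.763 for olfactory receptors, keratins and protocadherins and 0.991 for splicing factors and interferon response with an estimated correlation. With trended offsets splicing factors kept their call (adjusted p = 0.0315) and the others did not (median 0.21, adjusted p = 0.14 for olfactory receptors; -0.11, 0.14 for interferon response; 0.30, 0.0988 for keratins; -0.23, 0.0566 for protocadherins). Cholesterol synthesis was lower there (-0.14, adjusted p = 0.0315; 0.281 with TMM factors). Adjusted p = 0.465 for both splicing factors and cholesterol synthesis with trended offsets and an estimated correlation. Over assigned regions, endocrine transcription factors (0.15, adjusted p = 0.0342; trended 0.13, adjusted p = 0.0179) and olfactory receptors (0.21, adjusted p = 0.0342; trended 0.10, adjusted p = 0.392) were higher. Adjusted p = 0.32 and 0.934 for them with an estimated correlation. Olfactory receptors lost their gene-end call without empty vector replicates 1 and 2 (0.445 and 0.356) and Atrx shRNA replicate 3 (0.815), at medians of 0.24 to 0.28. The calls at 0.0476 ended without any 1 Smndc1 shRNA library (0.0501 to 0.0542), with medians close to those above. Those given here also ended without empty vector replicate 1 (keratins 0.557, interferon 0.178), empty vector replicate 2 (keratins 0.153, protocadherins 0.0685) and empty vector replicate 3 (protocadherins and splicing 0.775, interferon 0.366). The same holds for Atrx shRNA replicate 1 (protocadherins and interferon 0.425, splicing 0.776), Atrx shRNA replicate 2 (keratins 0.436, protocadherins and splicing 0.131) and Atrx shRNA replicate 3 (keratins 0.142, interferon 0.112). In some of these fits the median grew: protocadherins -0.35 and interferon -0.22 without empty vector replicate 3, and keratins 0.39 without Atrx shRNA replicate 3. In others it shrank: keratins 0.08 without empty vector replicate 1 and interferon -0.02 without Atrx shRNA replicate 3. The splicing median turned negative without empty vector replicate 3 (-0.10) and Atrx shRNA replicate 1 (-0.09). The assigned endocrine call ended without empty vector replicates 1, 2 and 3 (0.0802, 0.296 and 0.112), Atrx shRNA replicates 2 and 3 (0.229 and 0.0805) and Smndc1 shRNA replicate 2 (0.0578). Its medians there were 0.10 to 0.17. The assigned olfactory call ended without empty vector replicates 1 and 2 (0.586 and 0.296), Atrx shRNA replicates 2 and 3 (0.0816 and 0.64) and Smndc1 shRNA replicate 2 (0.0578). Medians for it there were 0.07 to 0.20.

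Among classes of region, those on the X chromosome were lower with Smndc1 shRNA (median -0.16, adjusted p = 2.49e-05) and with Atrx shRNA (-0.11, adjusted p = 0.00232). X holds 1.70 ± 0.158% and 1.75 ± 0.153% of counts, against 1.84 ± 0.191% with empty vector. The calls are lost with an estimated correlation (adjusted p = 0.952 and 0.916). Without empty vector replicate 1 the X medians are -0.06 (adjusted p = 0.0671) and -0.03 (0.577). The Smndc1 call also ended without Smndc1 shRNA replicate 3 (-0.04, 0.171), and the Atrx call without empty vector replicate 2 (-0.07, 0.247) and Atrx shRNA replicate 3 (-0.01, 0.82). Minimum-width regions were higher with Smndc1 shRNA (0.15, adjusted p = 1.21e-07) and Atrx shRNA (0.12, adjusted p = 5.38e-06). Those of middle width were lower (-0.12 in both, adjusted p = 1.7e-07 and 1.91e-06). Adjusted p = 0.952 and 0.811 with an estimated correlation for Smndc1 shRNA and 0.916 for both with Atrx shRNA. With trended offsets the minimum-width medians shrink to 0.06 (adjusted p = 0.18) and 0.03 (0.313) and the calls are lost, while the middle-width ones keep theirs (adjusted p = 0.00546 and 0.0148). With trended offsets and an estimated correlation, minimum width is called (adjusted p = 0.00873 and 0.0185) and middle width is not (0.098 and 0.0876). The minimum-width calls ended without empty vector replicate 1 (0.07, adjusted p = 0.0658, and 0.02, 0.577), without Smndc1 shRNA replicate 3 (0.05, 0.095) and, with a change of sign, without Atrx shRNA replicate 3 (-0.04, 0.82). The middle-width call for Atrx ended without empty vector replicate 1 (-0.07, 0.062) and Atrx shRNA replicate 3 (-0.06, 0.188). Gene ends, gene bodies, regions between genes, the distal 5 Mb of chromosomes, bodies of Zfp genes and wide regions were not called in either comparison with TMM factors (lowest adjusted p = 0.0587).

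**Figure D2:**
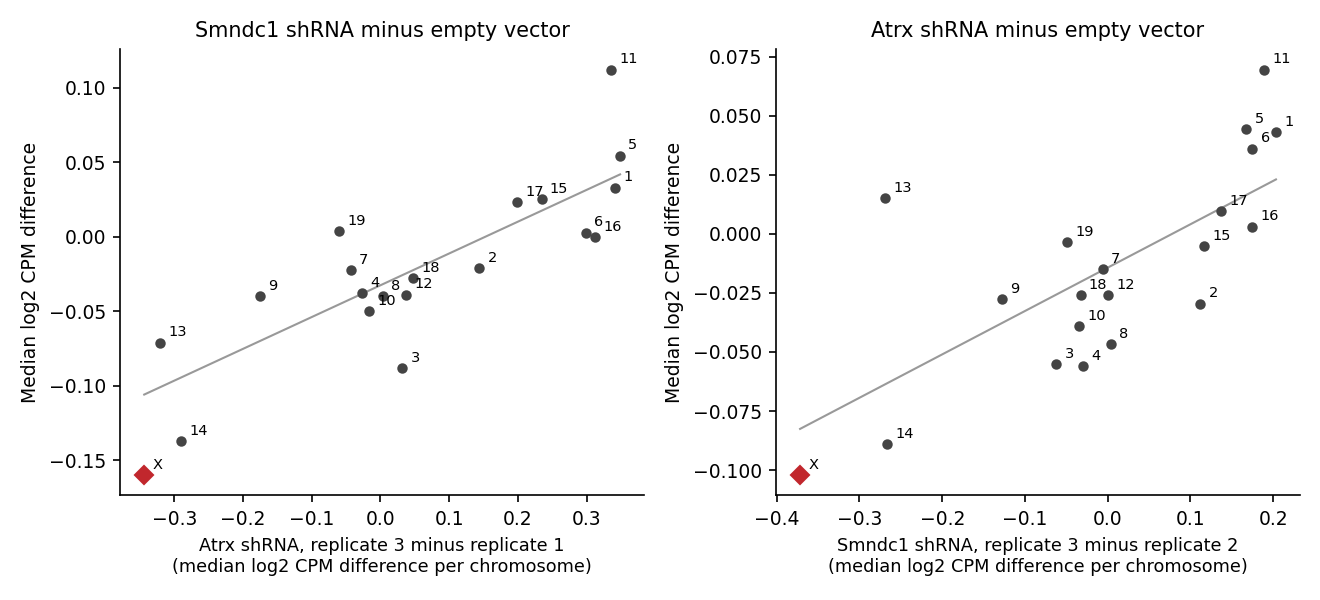
Median log2 CPM shift of each chromosome, Smndc1 shRNA minus empty vector (left) and Atrx shRNA minus empty vector (right), against the shift from a high-contrast to a low-contrast library of the group not compared. The line runs through the 19 autosomes. X lies at -0.16 and -0.10, and r over the autosomes is 0.807 and 0.655.

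Set against each other, the knockdowns differ at Gcg. Its end region stood at 39.1 ± 8.12 CPM with Smndc1 shRNA and 19.6 ± 1.51 with Atrx shRNA (trended 1.01 ± 0.16, adjusted p = 4.17e-06, higher in 3 of 3 libraries, called in 9 of 9 fits without 1 library). With TMM factors it has adjusted p = 0.121. A region 48.8 kb from Dppa2 was lower with Smndc1 shRNA (-1.79 ± 0.24, adjusted p = 6.27e-06). Regions inside Dbnl (1.56 ± 0.24, adjusted p = 0.000188) and Camkmt, a calmodulin methyltransferase gene (22.7 ± 5.47 against 8.03 ± 1.43 CPM; 1.49 ± 0.24, adjusted p = 0.000719), were higher. The ends of Ccn3 (-1.20 ± 0.26), Zc3h10 (-1.11 ± 0.23) and Alkbh3, a DNA repair demethylase gene (-1.12 ± 0.24), were lower, so that Zc3h10 and Ccn3 differ from both other groups.

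In that comparison 18 regions were higher and 43 lower with TMM factors, and 163 and 309 with trended offsets, where all 61 are called too. The rule also names regions inside Fam83g/Slc5a10 (1.54) and Lgr4 (-2.11) and near Hsfy2 (-1.60). With trended offsets it adds the ends of Fsbp (1.02 ± 0.18, adjusted p = 0.000149), Rspo3 (1.01), Prss35 (by TMM-normalised CPM, 2 of 3 libraries lie above all 3 of Atrx shRNA) and Mical1 (-1.51) and regions inside Pld1 (2.18) and Tmem178 (-2.31). It also adds regions far from genes, 339.66 kb from Cypt14 (1.96), 155.62 kb from Flrt2 (1.86) and 437.94 kb from Vrk2 (-2.08), the last called in 0 of 9 fits without 1 library (highest adjusted p = 0.305). List members that differ with TMM factors are Mcts2, an imprinted gene (1.30 ± 0.26, adjusted p = 0.0287), and Tal1 (1.02 ± 0.23, adjusted p = 0.0474), on the endothelial list. Other list members, called in at least 1 of the 2 fits, were lower with Smndc1 shRNA than with Atrx shRNA. They are Foxa2 (25.0 ± 4.70 against 37.4 ± 5.97 CPM), Myt1 (11.1 ± 1.24 against 20.4 ± 0.81) and Glis3 (3.42 ± 1.74 against 8.71 ± 0.752). In each, 3 of 3 libraries lie below all 3 of Atrx shRNA. This Foxa2 region is not the 1 that rose against empty vector. Of the key regions 1 was higher with trended offsets, at Gcg (1 adjusted over the list alone). EdgeR with TMM factors called 0 (1 adjusted over the list alone; 4337 of all regions had an unadjusted p under 0.05). The count of 61 became 5 and 18 without empty vector replicates 1 and 2, 107 without its replicate 3, and 3 and 25 without Smndc1 shRNA replicates 1 and 2. It became 4, 1 and 92 without Atrx shRNA replicates 1, 2 and 3, 614 with the replicate number as a block and 289 without replicate 3 of every group. Singled out after their values were seen, the calls made without Smndc1 shRNA replicate 1 are Dbnl, Dppa2 and Camkmt. Those without Atrx shRNA replicate 1 are the same regions and 1 near Stxbp5l (-1.33), and that without Atrx shRNA replicate 2 is Dppa2 (-1.83). Those without empty vector replicate 1 are Dbnl, Dppa2, Camkmt, Trdn (-1.40) and Sema4b (1.23). With trended offsets 472 became 306, 291, 171, 137 and 129 without empty vector replicates 1 and 2, Smndc1 shRNA replicate 1 and Atrx shRNA replicates 1 and 2.

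Fold changes against empty vector of the knockdowns correlate across the 80345 regions with r = 0.572. By comparison, 20 simulations of unchanged groups against the same 3 controls gave a mean of 0.489 and a highest value of 0.494. Regions are not independent replicates, and in those with a mean count of at least 50 the observed 0.484 lies under the simulated 0.492. The covariance is 0.108 against a simulated 0.0854 (highest 0.0866), and 0.038 against 0.0312 at that mean count. With trended offsets r is 0.558 against 0.497 (highest 0.505) and the covariance 0.125 against 0.0845 (highest 0.087). With trended offsets 48 regions were higher with both shRNAs and 13 lower with both. Independent lists of these sizes would share 0.655 and 0.414, a value that leaves out the shared controls. In 4 simulated fits of unchanged groups 0 were called with both, but those fits called at most 0 and 2 regions, too few to measure an overlap. Among the higher ones are the Irx1, Nkx6-1, Cdkn1a, Bbc3, Srsf1, Zfp239 and Snap47 regions described above. In 1 region the calls were opposite, the 1 near Dppa2 (-0.86 ± 0.23 with Smndc1 shRNA, 0.92 ± 0.21 with Atrx shRNA), chosen after its values were seen. Both comparisons use the same controls, which by itself makes the fold changes correlate, and 3 control libraries cannot be divided into groups of 2. The simulated correlations and covariances already include the shared controls but drew libraries independently, so the cause of the excess over them is open. The excess of the overlap over independent lists may come from the shared controls, and the overlap of calls is no measure of a shared effect. The control is an empty vector and no control shRNA is among the groups, so changes common to both shRNAs cannot be assigned to the targeted genes.

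**Figure D3:**
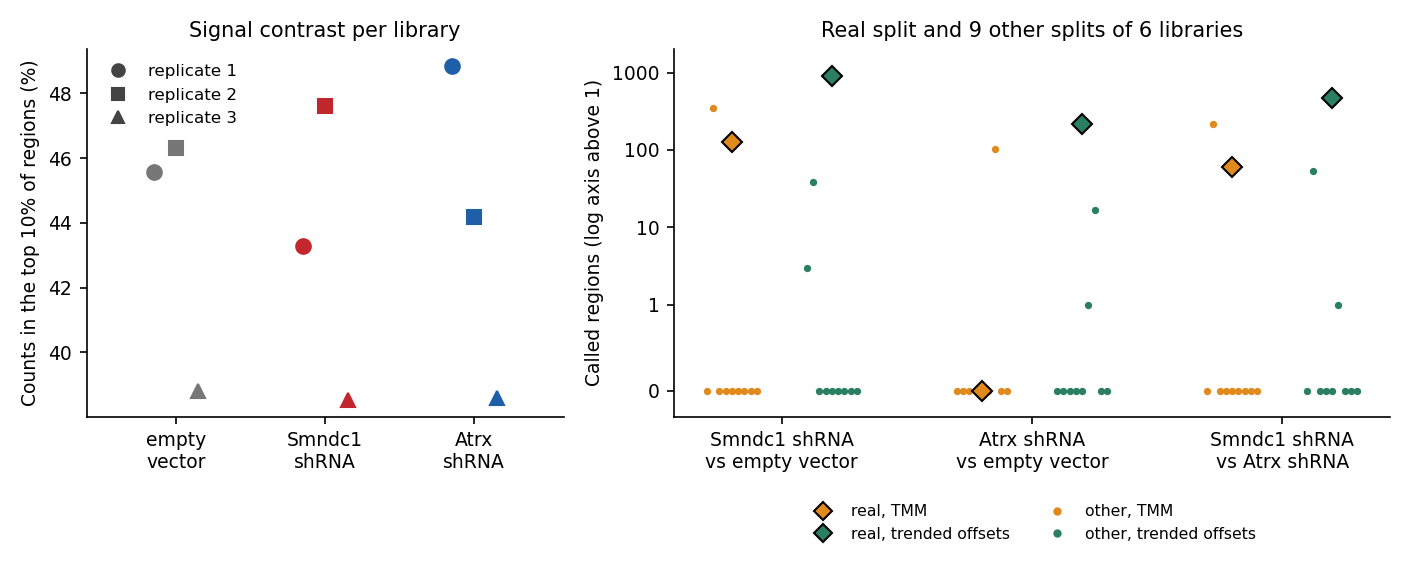
Left, percent of counts in the strongest 10% of regions in each library. Right, regions called in the real split of the 6 libraries of a comparison and in the 9 other splits, with TMM factors and with trended offsets. For Smndc1 shRNA against empty vector the real split calls 125 and the highest other split 345 with TMM factors, against 907 and 39 with trended offsets.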

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

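The tests weighed here were set against technical explanations only after the results were seen. The comparison of the knockdowns, the plain fit with trended offsets, camera with an estimated correlation and the fits without 1 library were planned.

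What draws attention is a tested difference between the knockdowns: 61 regions were called between Smndc1 shRNA and Atrx shRNA. The fit includes the controls, and the count became 5, 18 and 107 without empty vector replicates 1, 2 and 3. It became 3 and 25 without Smndc1 shRNA replicates 1 and 2, and 4, 1 and 92 without Atrx shRNA replicates 1, 2 and 3. A split that sets Atrx shRNA replicates 1 and 2 and Smndc1 shRNA replicate 2 against the rest called 217. The named ones include the ends of Ccn3 (-1.20), Alkbh3 (-1.12) and Zc3h10 (-1.11). The others are regions inside Dbnl (1.56), Fam83g/Slc5a10 (1.54), Camkmt (1.49) and Lgr4 (-2.11), and near Dppa2 (-1.79) and Hsfy2 (-1.60). Each lies beyond the other group in all 3 libraries, which the naming rule requires. The endothelial list was higher with Smndc1 shRNA over assigned regions (median 0.19, adjusted p = 0.0307; trended 0.20, adjusted p = 0.0699), and adjusted p = 0.973 with an estimated correlation. The call ended without Atrx shRNA replicates 1 and 2 (0.478 and 0.189) and Smndc1 shRNA replicates 1 and 3 (0.177 and 0.75). Of 9 classes of region 0 were called between the knockdowns by camera with TMM factors (lowest adjusted p = 0.702) or trended offsets (0.549). With trended offsets and an estimated correlation, regions between genes were called lower with Smndc1 shRNA (median -0.01, adjusted p = 0.0232).

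At gene ends the interferon response genes were higher (median 0.20, adjusted p = 0.00613) and the splicing factor genes lower (-0.14, adjusted p = 0.00945) with Smndc1 shRNA than with Atrx shRNA. Adjusted p = 0.959 for each with an estimated correlation. At the preset correlation of 0.01 both calls held with trended offsets (camera adjusted p = 0.0115 and 0.0045). That argues against dependence on abundance as the cause of the calls made at that preset only. The estimated correlations are 0.17 for interferon genes and 0.76 for splicing factors, so the held calls do not show a shift beyond replicate spread. For splicing factors, 1 library remains a candidate explanation: the median is 0.02 without Smndc1 shRNA replicate 3 (adjusted p = 0.728) and 0.01 without Atrx shRNA replicate 1 (0.416). The call also ended without Smndc1 shRNA replicate 1 (-0.13, 0.0512), but with a median near that of the full fit, so this loss does not bear on that explanation. For interferon genes this stays open: the median nearest 0 is 0.106. The call ended without Atrx shRNA replicate 1 (0.24, adjusted p = 0.119) and Smndc1 shRNA replicates 1 (0.18, 0.0512) and 3 (0.25, 0.0593). Medians in those fits are near the 0.20 of the full fit, so the lost calls by themselves do not point to 1 library. Members that vary together between replicates may account for both, since both calls are lost with an estimated correlation; an effect of the knockdowns is not excluded.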

How the results depend on the processing

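Leaving out replicate 3 of every group, all combinations with trended offsets other than the plain fit, and naming regions from that fit were chosen after seeing the data; the other alternatives were planned. For Smndc1 shRNA against empty vector, the 125 regions became 907 with trended offsets, 25 with DESeq2, 11 with limma voom, 291 with a mean count of at least 50, and 189 with 6 libraries. They became 1268 with the replicate number as a block, 27 at an adjusted p under 0.01 and 614 without replicate 3 of every group, and 1 to 609 with 1 library left out. For Atrx shRNA, 0 became 216, 0 (DESeq2), 0 (limma voom), 2, 18, 231, 0 and 91 in that order, and 0 to 22 with 1 library left out. The 2 lie inside Fignl1 (1.10 ± 0.19) and near Rdm1 (1.04 ± 0.16), named after their values were seen. Without empty vector replicate 3 the calls were 3, at Snap47 (2.24), near Itga3 (1.95) and at Apom (1.54). For Smndc1 shRNA against Atrx shRNA, 61 became 34 with DESeq2 size factors in edgeR, 472 with trended offsets, 16 with DESeq2, 7 with limma voom, and 134 with a mean count of at least 50. They became 614 with the block, 3 at an adjusted p under 0.01 and 289 without replicate 3 of every group, and 1 to 107 with 1 library left out. With trended offsets, 907, 216 and 472 became 2090, 801 and 1138 with the block, and 227 to 1155, 19 to 451 and 129 to 509 with 1 library left out. Without replicate 3 of every group they became 1023, 389 and 497. The replicate numbers pair the samples in part at most: 5 of 9 same-numbered pairs correlate above 0.1 (-0.039 to 0.419). Among libraries, 5 of 9 correlate best with their own number. Pairs of replicate 3 correlate at 0.313 to 0.419. The correlation of the responses, 0.572, was 0.558 with trended offsets and 0.484 with a mean count of at least 50. Of 1545 values of 103 single-region results, 1257 kept their side of the threshold, 122 lost it, 166 gained it and 0 reversed. Of 356 values of 21 list and class results, 200 kept it, 152 lost it, 3 gained it and 1 met the opposite direction in camera, which sets members against the other regions: minimum-width regions with Atrx shRNA at -0.04 without Atrx shRNA replicate 3 (0.26 without its replicate 1). The medians of splicing factors at gene ends changed sign as well, as their calls were lost: from 0.07 with Atrx shRNA against empty vector to -0.09 without Atrx shRNA replicate 1 and -0.10 without empty vector replicate 3, and from -0.14 with Smndc1 shRNA against Atrx shRNA to 0.01 without Atrx shRNA replicate 1 and 0.02 without Smndc1 shRNA replicate 3. With TMM factors and an estimated correlation all 19 results called with TMM factors lost their call; the other 2 of the 21, cholesterol synthesis in each comparison with empty vector, are called with trended offsets alone and were not called there either. A stricter threshold lowers counts by construction; for the other changes, the higher counts with fewer libraries included, the cause was not tested. Corrections on base composition, motif settings and exon classes were not run for want of a genome, and keeping all contigs moves nothing, as the table holds none. In the test on simulated data 25 of 100 changes of 2-fold were called with TMM factors and 33 with trended offsets. Changes of that size can thus go undetected with 3 libraries per group at this depth and spread, whose shares in this were not told apart.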

Other observations

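The tests of explanations and of other splits below were chosen only after the results were seen; the fit with trended offsets was planned.

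Smaller groups of called list members follow, with trended offsets where no other fit is named. With Smndc1 shRNA a region near Ldha, the lactate dehydrogenase gene (-1.53 ± 0.38), and 1 in Slc16a3, a lactate transporter gene (-0.66 ± 0.16), fell while 1 near Eno1, an enolase gene (0.91 ± 0.23), rose. Of 83 regions of glucose metabolism 1 rose and 2 fell (1 and 2 adjusted over the list alone; 0 and 0 with TMM factors). Imprinted genes had 3 higher and 0 lower of 164 (4 and 0 adjusted over the list alone; 0 and 0 with TMM factors): Dlk1 (1.35 ± 0.34), Mcts2 (0.88 ± 0.23) and Gnas (0.56 ± 0.15). Zfp genes had 7 higher and 2 lower of 1023 (7 and 2 adjusted over the list alone; 0 and 1 with TMM factors). Zfp518b is at -1.06 ± 0.14 (adjusted p = 4.36e-09, called in 9 of 9 fits without 1 library; -1.13, adjusted p = 0.0274 with TMM factors). There were 4 higher and 0 lower with Atrx shRNA (4 and 0 adjusted over the list alone; 0 and 0 with TMM factors). With Smndc1 shRNA, Fos (-0.52, called in 6 of 9 fits without 1 library), Skil (-0.63, 5 of 9), Col1a1 (-0.50, 6), Usp18 (-0.97, 3), Krt7 (-0.85, 4) and Ptprn2 (-0.91, 1) were lower. Hhex (0.81, 6), Hsp90b1 (0.59, 3), Smarcd3 (0.97, 3), H3f3a (1.53, 1) and Cacna1c (0.53, 3) were higher. Without empty vector replicate 2 all 11 calls ended (adjusted p = 0.0912, 0.0551, 0.107, 0.467, 0.0683, 0.2, 0.163, 0.513, 0.13, 0.154 and 0.221 in that order). With Atrx shRNA Mvk (0.51, 4 of 9) and Rims2 (0.93, 3) were higher and Sox18 (-0.66, 3) lower, and these calls ended without empty vector replicate 1 (adjusted p = 0.226, 0.396 and 0.142). Between the knockdowns, U2af2, a splicing factor of the branch site complex (-0.56 ± 0.12, adjusted p = 0.00408), and a region near Gadd45a (-0.61 ± 0.13, adjusted p = 0.00145) were lower with Smndc1 shRNA and Krt84 (0.85 ± 0.15, adjusted p = 0.000246) higher, all in 9 of 9 fits without 1 library. Vgf (-0.53, 5 of 9), Cdh2 (-1.03, 2) and Rps18 (-0.60, 6) were lower, Spp1 (0.96, 4) and Map2 (1.35, 5) higher, and Rbfox3 had regions at -0.83 (7), 0.65 (3) and 1.08 (3). Of these, the lower Rbfox3 region lost its call without Atrx shRNA replicate 3 (adjusted p = 0.129) and the others without Atrx shRNA replicate 2 (0.0984, 0.127, 0.0984, 0.196, 0.235, 0.347 and 0.183 in that order). The calls at Ldha, Slc16a3, Eno1, Dlk1, Mcts2 and Gnas ended without empty vector replicate 1 (adjusted p = 0.164, 0.0779, 0.0679, 0.205, 0.375 and 0.132), and most calls named here with under 9 of 9 fits, or with no count, also ended without other libraries.

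At gene ends 22 lists were called in no comparison with TMM factors (lowest adjusted p = 0.0929) or trended offsets. Their medians with Smndc1 and Atrx shRNA are: alpha identity 0.07 and 0.02, beta identity -0.23 and -0.07, endocrine transcription factors 0.06 and 0.15, exocrine and ductal -0.22 and -0.14, and hepatic and intestinal 0.17 and 0.09. Next are mesenchymal 0.06 and -0.13, immune 0.21 and -0.01, neuronal -0.03 and -0.04, secretory machinery 0.04 and 0.02, glucose metabolism 0.02 and -0.08, and imprinted genes 0.08 and 0.03. For the others they are p53 targets -0.04 and 0.11, unfolded protein response -0.06 and -0.02, immediate early genes -0.07 and 0.01, cell cycle -0.09 and -0.04, telomere and DNA repair -0.06 and -0.06, and chromatin remodelers -0.04 and 0.05. Last are NFkB inflammation 0.01 and -0.14, hippo and TGFb targets -0.13 and 0.02, Hox -0.01 and 0.15, Zfp -0.02 and -0.05 and ribosomal proteins -0.09 and -0.01. The other islet hormones, tested over assigned regions alone, have 0.11 (adjusted p = 0.85) and 0.09 (0.824), and the histone list matched 0 genes.

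More regions were lower than higher with Smndc1 shRNA, 87.2% of calls with TMM factors. Library contrast that depends on abundance is argued against as the whole cause, since 63.3% of calls are lower with trended offsets (55.7% to 72.7% without 1 library), though the share moved toward balance. These offsets leave the weakest 10% of regions shifted (median -0.10), but 3 higher and 6 lower calls lie there, and 63.3% of the others are lower. A trend along gene-poor and gene-rich stretches, as base composition would give, may contribute: the lower share is 43.7% in the most gene-rich quintile (37.0% to 50.7%, 95% confidence interval) and 73.3% in the most gene-poor. The interval is binomial over called regions, which are not independent replicates, and does not measure the spread between libraries. Base composition itself was not measured, and an effect of the knockdown stays open.

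Regions on X were lower with both shRNAs. Abundance is argued against as the whole cause, since the medians with trended offsets are -0.13 (adjusted p = 0.00213) and -0.10 (0.0348), though adjusted p = 0.515 and 0.879 there with an estimated correlation. Background reads in proportion to chromosome copies remain a candidate that was not settled. Across the 19 autosomes the shift follows that between libraries of high and low contrast (r = 0.807 and 0.655 across chromosomes, which are not independent replicates). X lies -1.62 and -0.625 residual SD from that line. The slope of that line was fitted freely and chromosome copies were not measured, so the line cannot show that background is enough. By group mean, the share of counts in the strongest 10% of regions is not lower with Atrx shRNA than with empty vector. It is 43.9 ± 5.13% and 43.6 ± 4.14%, against 43.1 ± 4.53% with Smndc1 shRNA. With TMM factors, though, weak regions were higher and most strong ones lower by median log2 fold change, which is lower contrast. In bins 1 (weakest), 7 and 10 of 10 by abundance the medians are 0.16, -0.09 and 0.002 with Atrx shRNA. With Smndc1 shRNA they are 0.14, -0.07 and -0.04. Their spread between libraries was not measured, and the share alone does not weigh against background. An effect of either knockdown on X was neither shown nor excluded.

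With 3 libraries against 3 there are 10 splits, so no share under 0.1 can be had. With TMM factors, 2 of 10 splits called as many regions as the real 1 for Smndc1 shRNA against empty vector (125; highest other 345) and 2 for Smndc1 shRNA against Atrx shRNA (61; 217). For Atrx shRNA against empty vector the real split called 0, so 10 of 10 do so by construction (highest other 103). For Smndc1 shRNA against empty vector the highest other split sets empty vector replicates 1 and 2 and Smndc1 shRNA replicate 2, libraries of high contrast, against the rest, which points to a structure of the samples. The highest ones in the other comparisons do the same. With trended offsets 1 of 10 splits, the real 1, called as many in each comparison (907 against 39, 216 against 17 and 472 against 54).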
